A study of Rattus norvegicus with 6 samples.

How the data were processed

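Circular RNA (circRNA, RNA closed into a covalent ring by back-splicing) was measured in 6 lung samples of male rats on 1-colour Agilent-format arrays made by Arraystar, 1 array per sample. Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA and spares circles, and the remaining RNA was amplified with random primers into Cy3-labelled cRNA. The scanner files hold the deposited intensity of each spot as extracted with Agilent Feature Extraction 11.0.1.1, per the file headers: a processed signal, background-subtracted and set to a small positive floor where it would fall below 0, with no scaling between arrays, and the median brightness of the spot and its local surround. They also hold the software's yes-or-no marks per spot, among them whether a spot lay well above background. The authors' processed table holds log2 values for 14145 circRNA probes, and limma is named in the submitters' processing notes with no step or version given. Its columns had medians between 6.06 and 6.08 and the same maximum of 17.6, as after quantile normalization, and over circRNAs well above background they rose by 0.977 to 1.19 per doubling of the array's own median spot brightness (Pearson's r of at least 0.987), so the scale is log2 with higher values for brighter spots, and the background treatment stays unknown. That table was used as an alternative only, and 0 columns of values per sample were left without a sample.

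Control spots and spots marked as non-uniform or as population outliers (25 to 61 per array, of which 1 to 6 were circRNA spots) were left out, and log2 signals of spots of 1 probe were averaged, which gave 14227 probes. Because 73.5% of these values lay well above background, each array's 75th percentile over all these probes was subtracted from its log2 processed signals. All levels below are on this scale, where 0 is the array's own 75th percentile. The 11280 circRNAs well above background on at least 3 of the 6 arrays entered the test, and 2 further ones were left out because marked spots left too few values in a group. MCT was compared with saline with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 arrays, no covariate), with Benjamini-Hochberg adjustment over the tested circRNAs and a threshold of 0.05. A looser criterion, an unadjusted p below 0.05 with a fold of at least 1.5, was counted beside it. A circRNA not well above background on any array of a group has only a bound there: the bright group's mean was set against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal. No spot was saturated. On simulated data with the means and spreads of the 11280 circRNAs, 200 of them changed per run and 5 runs, the test of MCT against saline recovered 7.2% of 2-fold, 74.4% of 4-fold, 99.6% of 8-fold and 99.6% of 16-fold changes, with a mean of 10.6 false calls per run. The simulation drew independent errors, which real arrays do not have. It also gave both groups the same spread, had no signal floor, and its 200 true changes eased the adjusted threshold. The recovered shares need not hold for the real data: ASCRPR012567, 15.1-fold higher in MCT, had a limma adjusted p of 0.20.

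The design, the alternatives and the rule for named circRNAs were fixed before the data were examined. The rule took in each direction the 12 circRNAs with the largest difference among those past the threshold without overlap between the groups. Where fewer passed, it was filled up with those of the smallest unadjusted p at a fold of at least 1.5, also without overlap. Neither the files nor the table of gene names used here pairs the circRNA probes with host genes, so the circRNAs are given by array ID, 2 per direction, and the 23 lists of host genes that had been fixed in advance were not tested. The array also carries 62 probes of linear transcripts with 10 spots each, whose accessions were matched without versions to a RefSeq table of assembly GRCr8, and 39 received a symbol. The 31 linear probes well above background on at least 3 arrays were fitted as the circRNAs were, with adjustment over these 31, a comparison added after seeing the data. No coordinates are given, because the array design names an older build.

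The headers place saline 1, saline 2, saline 3 and MCT 1 on 1 slide scan (slide 1) and MCT 2 and MCT 3 on another (slide 2), so that slide was fitted as a block and the comparison was repeated within slide 1. As slide 2 holds no saline array, both give the same differences, those of MCT 1 against the saline arrays, and differ only in the estimate of the spread. The labels number replicates 1 to 3 in both groups without naming a shared litter, batch or day. Alternatives were quantile normalization, no scaling, a percentile over probes seen on all arrays, normexp background correction (offset 50, on the median signal because the files hold no mean signal) followed by quantile normalization, no filter or a stricter filter on dim probes, the authors' table, array weights, a trended and robust variance prior, the slide, the replicate number, and each array left out in turn. Arrays have no read depth. Their number limits the precision: the median standard error of a circRNA's difference was 0.41 on the log2 scale, a 95% interval of ± 0.90, or 1.86-fold either way. Replicates are separate samples by their labels, and whether each came from its own rat is not spelled out, so p-values measure the spread between these samples.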

Results

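Lung tissue was profiled from male rats given 1 intraperitoneal dose of monocrotaline (MCT, 60 mg per kg) or saline and sampled 28 days later. Monocrotaline is a plant pyrrolizidine alkaloid whose liver metabolites injure the pulmonary endothelium, and the injected rat is a standard model of pulmonary arterial hypertension. There were 3 saline and 3 MCT samples, each on 1 array with probes for 14145 circRNAs. The design addresses which circRNAs differ in the lung 28 days after the dose. No measure of disease in these samples was used here.

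The MCT lungs gave fewer detected circRNAs than the saline lungs. On all 3 saline arrays 10834 circRNAs lay well above background, on all 3 MCT arrays 7344, and on all 6 arrays 7325. By the laxer mark of a positive and significant signal the counts were 12719 and 11020. In the saline lungs 257 circRNAs were detected on every array and on no MCT array, and 3 showed the reverse. Of the 257, 7 had a saline mean at least 2-fold above the detection limit of the MCT arrays, and all 3 of the reverse kind lay at least 2-fold above that of the saline arrays. After scaling, the mean limit was higher on the MCT arrays than on the saline arrays. The contrast between the 7 and the 3 therefore follows in part from array brightness. Brightness also went with the number of circRNAs detected. The 75th percentile of the processed signal was 93.9, 75.6 and 94.5 fluorescence units on saline arrays 1 to 3, and 41.4, 95.2 and 32.3 on MCT arrays 1 to 3. The share of circRNAs well above background was 80.3%, 80.3% and 84.5% on the saline arrays, 63.1% on MCT 1, 78.7% on MCT 2 and 55.1% on MCT 3. The mean of the negative controls lay between 16.3 and 19.6 units on all 6 arrays at the same detector voltage.

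**Figure D1:**
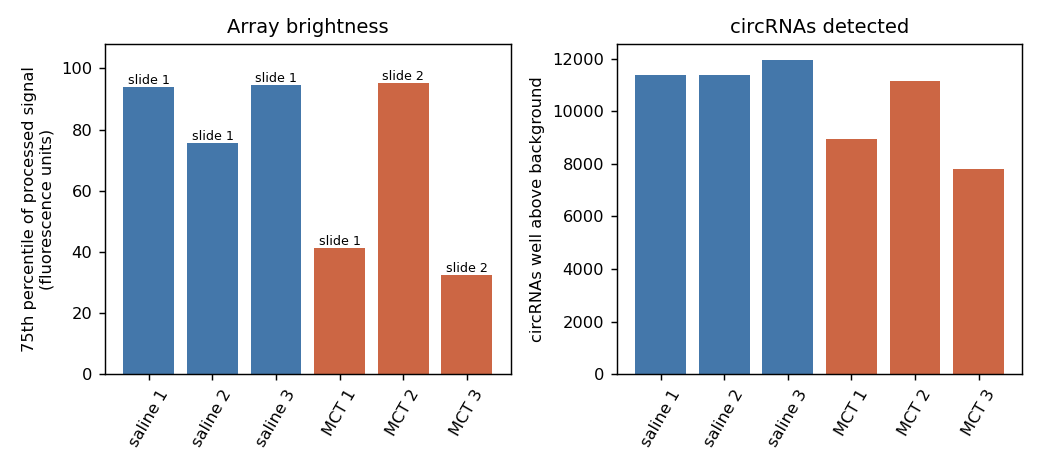
Left, 75th percentile of the processed signal of each array in fluorescence units, with the slide above the bar; right, number of the 14145 circRNAs well above background on each array. Blue bars are saline and orange bars MCT arrays; MCT 1 (41.4 units) and MCT 3 (32.3 units) are the dimmest, and MCT 2 (95.2 units) is as bright as the saline arrays.

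The saline arrays resembled each other more than the MCT arrays did. Over the 11280 tested circRNAs, Pearson's r of the scaled log2 signals was 0.96, 0.93 and 0.93 between saline arrays. Between MCT arrays it was 0.92 for MCT 1 with MCT 2, 0.88 for MCT 1 with MCT 3 and 0.85 for MCT 2 with MCT 3. MCT 2 correlated best with saline 3, at 0.96, although the 2 arrays lay on different slides. These correlations are across circRNAs, which are not independent replicates. The first principal component held 45.3% of the variance and set MCT 1 and MCT 3 apart from the other 4 arrays, MCT 2 included.

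**Figure D2:**
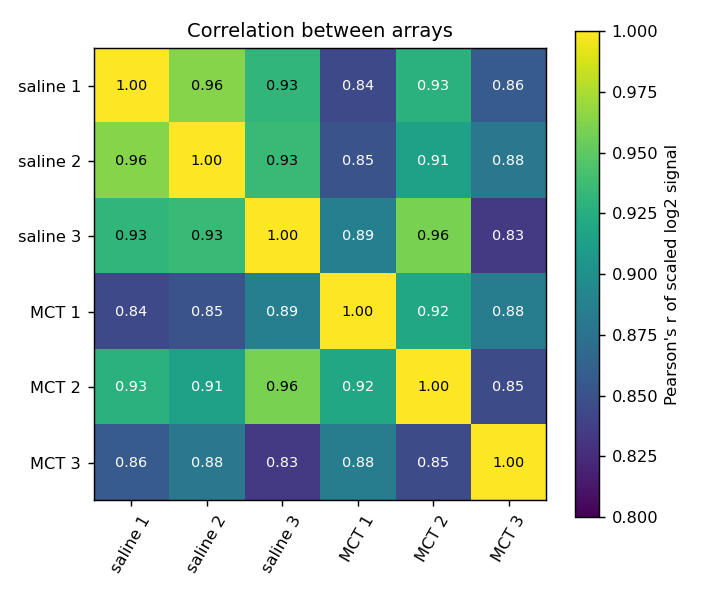
Pearson's r of scaled log2 signals between every 2 of the 6 arrays over the tested circRNAs, on a colour scale from 0.8 to 1.0. MCT 2 and saline 3 (0.96) lie as close as saline 1 and saline 2 (0.96).

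Between MCT and saline lungs, 2 circRNAs fell and none rose past an adjusted p of 0.05 (limma, 11280 tested, n = 3 against 3). ASCRPR004694 stood at 0.34 ± 0.58 (SD, n = 3) in saline lungs and lay below reliable detection on all 3 MCT arrays, with a measured mean of -4.15 ± 0.44 (SD, n = 3). Its processed signal was 91.1, 79.2 and 190.1 units on the saline arrays against 3.20, 4.00 and 1.79 on the MCT arrays. On this scale saline lungs therefore held at least 8.38-fold more. The p-value (limma adjusted p = 0.0048) belongs to the fitted difference of the measured means and not to this bound. It rests on 3 MCT values below reliable detection, and that of MCT 3 lay near the array's lowest signal (1.75 units). ASCRPR007618 fell from 1.36 ± 0.64 (SD, n = 3) to -2.48 ± 0.41 (SD, n = 3), a log2 difference of -3.84 ± 0.42 (SE), or 14.4-fold (limma adjusted p = 0.0130). It was well above background on only 1 MCT array, MCT 2, at 15.1 units against 161.7 to 402.9 units in the saline lungs, so that the size of the fold rests in part on 2 values below reliable detection. What genes these circles derive from is not named in the sources used here.

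Above the saline lungs, the smallest p-values belonged to ASCRPR011652 and ASCRPR013228, neither of which passed the adjusted threshold. ASCRPR011652 had a mean of -0.69 ± 0.25 (SD, n = 3) in saline and 2.28 ± 0.69 (SD, n = 3) in MCT lungs, a log2 difference of 2.97 ± 0.42 (SE), or 7.82-fold (limma adjusted p = 0.063). ASCRPR013228 had means of 0.19 ± 0.26 (SD, n = 3) and 2.73 ± 0.46 (SD, n = 3), a log2 difference of 2.54 ± 0.37 (SE), or 5.80-fold (limma adjusted p = 0.066). Even before scaling, the processed signals of both were higher on each of the 3 MCT arrays than on any saline array: 92.9 to 705.4 against 38.5 to 64.6 units for ASCRPR011652, and 149.4 to 795.0 against 80.1 to 133.0 units for ASCRPR013228. The fixed rule took 12 circRNAs per direction. Those higher in MCT differed by 1.81 to 3.92 on the log2 scale, and all 12 were measured in both groups on at least 1 array. Apart from the 2 that passed, limma adjusted p-values in both directions reached up to 0.26. Of the 12 lower ones, 8 were not well above background on any MCT array and were at least 1.06-fold to at least 8.38-fold lower, and the other 4 had log2 differences from -3.84 to -2.03.

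**Figure D3:**
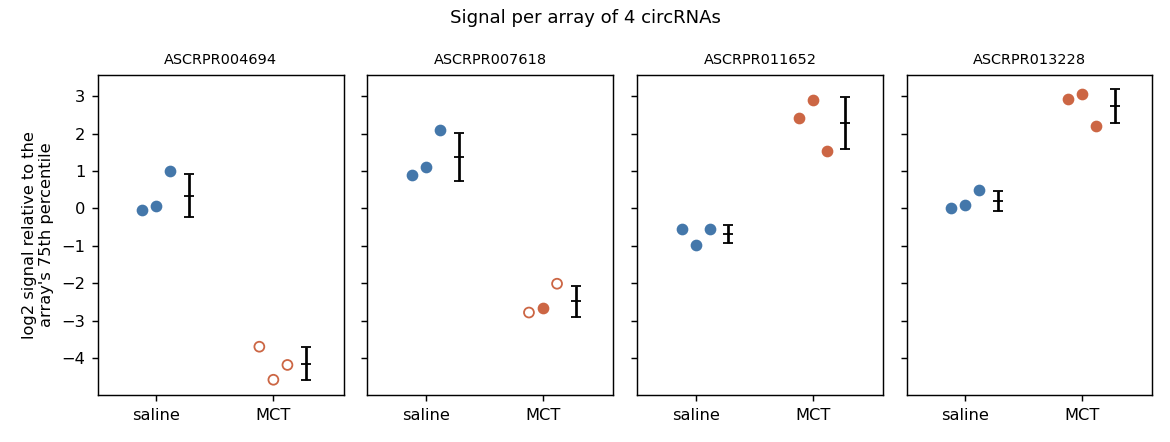
Log2 signal relative to the array's 75th percentile for the 2 circRNAs that fell (ASCRPR004694, ASCRPR007618) and the 2 with the smallest p among those higher in MCT. Circles are single arrays, open where the spot was not well above background; black bars are the mean and SD of 3 arrays. No MCT value overlaps a saline value in any panel, as the rule for named circRNAs required.

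The number of calls changed with single arrays and with the processing. The main count of 0 higher and 2 lower became 94 higher and 12 lower without MCT 2, 4 and 3 without MCT 3, and 0 and 1 without saline 3, where ASCRPR007618 still differed by -3.48 (limma adjusted p = 0.079). Slide 2 holds no saline array, so that with slide as a block and within slide 1 alike the differences are those of MCT 1, a single array, against the saline arrays. The count was 12 higher and 119 lower with slide as a block, and 71 and 113 within slide 1, where MCT 1 is assumed to vary as the saline arrays do. On MCT 1 both ASCRPR004694 and ASCRPR007618 lay below reliable detection, and ASCRPR011652 and ASCRPR013228 differed from saline by 3.11 and 2.73. In the authors' processed values no circRNA passed in either direction (limma adjusted p = 0.25 for ASCRPR004694 and ASCRPR007618, at fitted differences of -2.26 and -2.66). None passed either with normexp background correction of the median signal followed by quantile normalization (0.45 for both, at -1.31 and -1.78), while quantile normalization of the processed signal alone called both (0.040 and 0.043). Both fitted differences of ASCRPR004694 are smaller than its bound on the processed signal (3.07 on the log2 scale), so that bound depends on how the signal was processed. Array weights, whose estimate did not converge, gave 910 higher and 1524 lower. A block for the replicate number, which the labels tie to no shared litter, batch or day, gave 18 and 12. Over all settings tried, the adjusted p of ASCRPR004694 ran from 5.8e-05 to 0.45 and that of ASCRPR007618 from 0.00026 to 0.45.

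By the looser criterion, 553 circRNAs were higher and 749 lower in MCT lungs, and without scaling between arrays 47 were higher and 1528 lower. The lean to lower values also depended on the filter on dim probes. Among circRNAs well above background on all 6 arrays, 538 were higher and 455 lower, and with no filter 1433 and 738. All 1302 circRNAs with an unadjusted p below 0.05 also differed by at least 1.5-fold, and 564 would be expected by chance among 11280 independent tests. The 3 MCT values all lay above, or all below, the 3 saline values for 1656 circRNAs, 858 higher and 798 lower. They made up 14.7% of those tested, where chance gives 10% on average for 3 against 3. This share was not counted for the 9 other ways of splitting the arrays, so a surplus over chance was not shown. By the looser criterion 2 of the 9 other ways of splitting the 6 arrays 3 against 3 gave more circRNAs than the 1302 of the real groups, 1602 and 1410. The looser counts were 1455 higher and 1269 lower without MCT 2, 302 and 344 without MCT 1, 348 and 356 without saline 1, 359 and 363 without saline 2, and 326 and 855 without saline 3. Of the tested circRNAs 47.1% were higher in MCT, and the median log2 difference of -0.04 had p = 0.5 in an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1. The share turned above 50% in several settings, among them no filter on dim probes (54.3%), the filter on all 6 arrays (54.6%), without MCT 3 (54.7%) and without saline 3 (51.4%). Scaling sets both values: without it, 8.97% were higher and the median log2 difference was -0.84, and all differences here are relative to that shift.

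**Figure D4:**
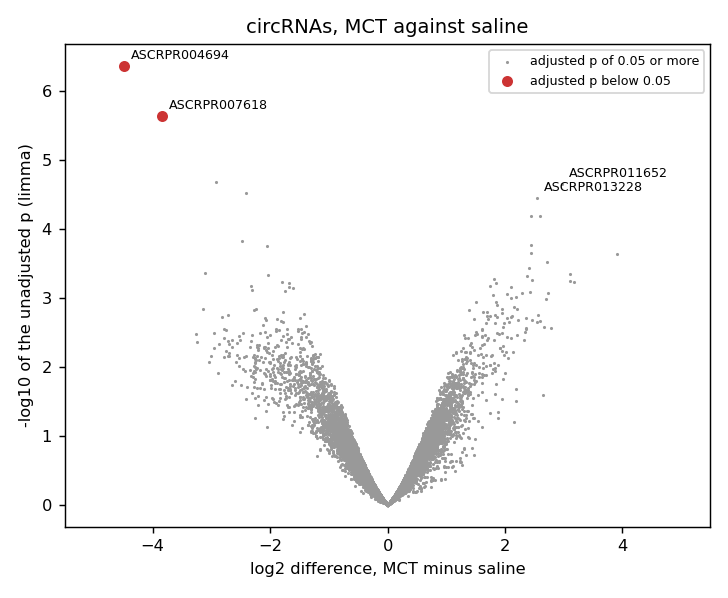
Log2 difference between MCT and saline lungs (x axis) against -log10 of the unadjusted limma p (y axis) for the 11280 tested circRNAs, one point each. The 2 red points, ASCRPR004694 and ASCRPR007618, passed an adjusted p of 0.05, and both lie on the side lower in MCT.

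Linear transcripts that remained after RNase R digestion could be named. None of the 31 tested linear probes changed at an adjusted p of 0.05 (limma), 5 had an unadjusted p below 0.05, and the median log2 difference was -0.19. Without MCT 2, or with a trended and robust variance prior, 1 passed. Of the 21 probes with a symbol (20 genes), 13 had lower and 8 had higher values in MCT lungs, and leaving out the scaling lowers all linear probes by the same amount, enough to put these 8 below 0. Among 9 probes of widely used reference transcripts, 7 had lower and 2 had higher values. The direction of these 2 rests on the scaling in the same way. The 7 lower values are likewise relative to the scaling, and leaving it out could only lower them further. Ldha, the lactate dehydrogenase A subunit, differed by -0.72 ± 0.27 (SE) at one probe and by -0.50 ± 0.32 (SE) at another. Pgk1, a glycolytic kinase, differed by -0.65 ± 0.28 (SE), the ribosomal protein transcript Rplp1 by -0.75 ± 0.34 (SE), Rpl13a by -0.32 ± 0.31 (SE), beta-actin (Actb) by -0.61 ± 0.39 (SE), beta-2-microglobulin (B2m) by -0.47 ± 0.32 (SE) and the mitochondrial succinate dehydrogenase subunit Sdha by -0.38 ± 0.29 (SE). The lysosomal beta-glucuronidase Gusb differed by 0.52 ± 0.44 (SE), and the chaperone Hsp90ab1, whose 95% interval ran from -0.69 to 0.70, by 0.01 ± 0.31 (SE).

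Genes outside the reference set gave no call either. Ndfip1, an adaptor of ubiquitin ligases, had the largest difference among the named linear transcripts at -0.96 ± 0.40 (SE), followed among these genes by the pyruvate dehydrogenase kinase Pdk3 at -0.72 ± 0.49 (SE). Higher values were measured for Odf2l (0.71 ± 0.51, SE), Pop7 (0.64 ± 0.36, SE), the Mediator subunit Med16 (0.44 ± 0.29, SE), the inflammasome sensor Nlrp3 (0.38 ± 0.44, SE), Map2 (0.30 ± 0.31, SE) and the synaptic scaffold Dlg4 (0.14 ± 0.27, SE), and slightly lower ones for the translation factor Eif4b (-0.19 ± 0.28, SE), Pdcd10 (-0.13 ± 0.48, SE) and the nucleoside transporter Slc28a2 (-0.11 ± 0.41, SE). Adjusted p-values of the named linear transcripts lay at 0.31 or above by limma. Of the lists fixed in advance, the one of hypoxia and glycolysis held 3 tested linear probes of 2 genes (Ldha at both probes and Pgk1), with lower values at all 3, and the one of inflammation and NF-kappaB held 1, Nlrp3, with a higher value. None passed, and the p adjusted over the list alone was 0.063 at the lowest for the first and 0.42 for the other by limma. Signals of linear transcripts here are what RNase R left, not their level in the tissue.

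**Figure D5:**
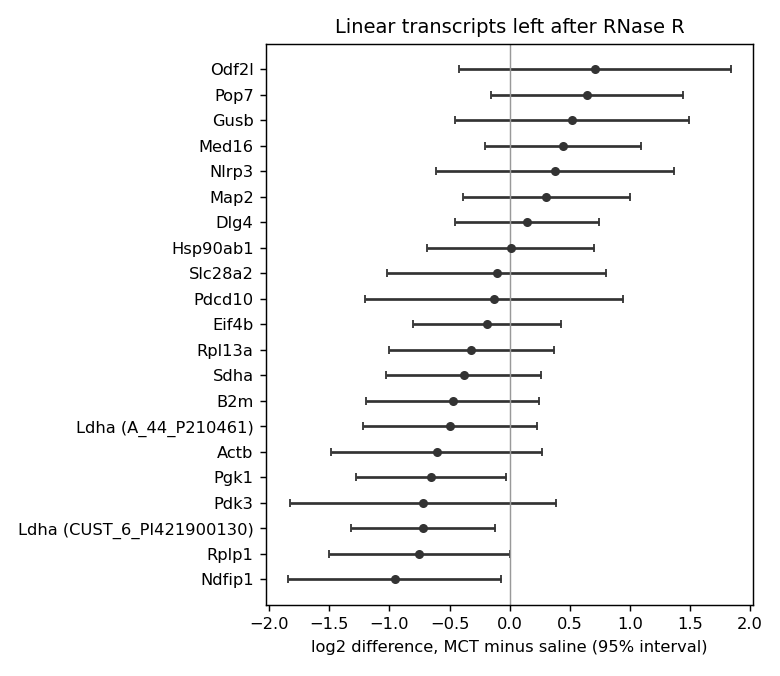
Log2 difference between MCT and saline lungs with its 95% interval (bars) for the 21 linear probes with a gene symbol, ordered by size. The intervals of Ndfip1, Rplp1, Pgk1 and 1 of the 2 Ldha probes exclude 0 before adjustment, and none passed after it.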

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

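Slide 1 alone and leaving out both dim arrays were chosen after the data were seen, as was the comparison of linear probes. The 4 named circRNAs kept their direction in each setting that tested them. ASCRPR004694, which has only a bound in MCT lungs, passed an adjusted p of 0.05 by limma in 15 of 18 settings, ASCRPR007618 in 13 of 18 (log2 differences -4.64 to -1.78), ASCRPR011652 in 7 of 19 and ASCRPR013228 in 6 of 19. These tallies are no measure of stability. For each of the 4 circRNAs, 4 of the passes came from the slide block, slide 1 alone, array weights and the replicate block. The slide block and slide 1 alone are 1 contrast of a single MCT array, and the array weights did not converge. The labels tie the replicate numbers to no shared litter, batch or day. Signal over background limits the sizes of the lower circRNAs, as 8 of the 12 taken by the rule were not well above background on any MCT array. Except where the construction of a setting shows it, the cause was not tested.

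Against 0 higher and 2 lower at an adjusted p below 0.05, and 553 higher and 749 lower by the looser criterion, the counts moved as follows. Without scaling, 1 was lower, and 47 were higher and 1528 lower by the looser criterion. With normexp and quantile normalization, 0 were lower, and 314 were higher and 368 lower by the looser criterion. With only circRNAs well above background on all 6 arrays, 0 were lower, and 538 were higher and 455 lower by the looser criterion, a balance turned to the higher side; ASCRPR004694 and ASCRPR007618 were not tested there. In the authors' values, 0 were lower. With no filter, 1433 were higher by the looser criterion. Array weights gave 910 higher and 1524 lower, and 1883 and 2154 by the looser criterion, from an estimate of weights that did not converge. The trended and robust prior called 1 higher circRNA and 1 linear probe. The slide as a block gave 12 higher and 119 lower, and slide 1 alone, with the same differences of MCT 1 from saline, gave 71 and 113, and 917 and 1361 by the looser criterion. Leaving out both dim arrays, which leaves MCT 2 as a lone sample assumed to vary like the saline ones, gave 0 lower, and 137 higher and 416 lower by the looser criterion. With 1 array left out in turn, 0 to 94 were higher and 1 to 12 lower, 302 to 1455 higher and 344 to 1269 lower by the looser criterion, and 0 to 1 linear probes passed.

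The replicate block gave 18 higher and 12 lower, and 368 higher by the looser criterion. The numbers did not pair the samples: the deviations of arrays with the same number correlated at -0.23, -0.36 and -0.45, and 0 of 6 arrays correlated best with their own number.

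The median log2 difference of the circRNAs, -0.04 with 47.1% higher, turned above 0 with no filter (0.064, 54.3% higher; linear probes 0.36), the filter on all 6 arrays (0.060, 54.6%), array weights (0.041, 52.3%), the slide as a block or slide 1 alone (0.00058, 50.1%) and without both dim arrays (0.076, 57.3%). With 1 array left out it ran from -0.14 to 0.058, and the share from 43.1% to 54.7%. The positive and significant mark in place of well above background gave 12719 circRNAs on all saline and 11020 on all MCT arrays, against 10834 and 7344, a smaller gap in the same direction.

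Several linear transcripts turned direction, none of them called. Without scaling these were Pop7 (-0.16), Med16 (-0.35), Odf2l (-0.089), Gusb (-0.28), Map2 (-0.49), Nlrp3 (-0.42), Dlg4 (-0.65) and Hsp90ab1 (-0.79). With the slide as a block and in slide 1 alone these were Nlrp3 (-0.29), Dlg4 (-0.035) and Pdcd10 (0.36), and without both dim arrays B2m (0.043), Pdk3 (0.30), Odf2l (-0.022), Gusb (-0.30), Pdcd10 (0.50) and Hsp90ab1 (-0.33). With 1 array left out, Slc28a2 ran from -0.52 to 0.21, Hsp90ab1 from -0.14 to 0.21, Pdcd10 from -0.45 to 0.43 and Nlrp3 from -0.12 to 0.71. The planned set test of host gene lists (camera) was not run, as no host gene is named.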

Other observations

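The tests on MCT 2 with bright circRNAs and with circRNAs chosen from other arrays, and the splits of the samples, were planned before their results were seen; the tests on brightness, exchanged labels, the signal floor and the probes without an accession were chosen only after the pattern was seen.

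Among circRNAs chosen from 4 arrays alone (MCT 1 and MCT 3 against saline 1 and saline 2, unadjusted p under 0.01 and at least 2-fold), 272 were higher and 354 lower in MCT, with a median size of 1.93 on the log2 scale. In MCT 2 minus saline 3, a pair that had no part in the choice, 82.7% of the 272 were higher and 79.9% of the 354 lower, but the median difference in that direction was 0.39. Over the remaining circRNAs MCT 2 lay above saline 3 in 50.8%. The choice on the 4 arrays inflates the 1.93, so the gap between the sizes is partly selection.

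MCT 2 sat nearer to saline 3 (r = 0.96) than to MCT 1 or MCT 3. Noise of dim signals on MCT 1 and MCT 3 is argued against. Over the 1829 brightest circRNAs MCT 2 still correlated better with saline 3 than with MCT 1 or MCT 3, by at least 0.10. Other noise of the 2 dim arrays, which bright circRNAs would share, was not tested. An exchange of the labels of MCT 2 and saline 3 is argued against, because saline 3 correlated better with both other saline arrays than with MCT 1 or MCT 3, by at least 0.045. Over the brightest circRNAs these correlations were 0.86 and 0.85 against 0.69 and 0.69. The measure alone does not sort the labels, as MCT 2 also correlated slightly better with saline 1 (0.928) than with MCT 1 (0.920). Saline 3 shared its slide with saline 1, saline 2 and MCT 1. In MCT 2 minus saline 3, 81.2% of the 626 chosen circRNAs went the way of the other MCT arrays. That share cannot exclude a saline lung under the MCT label, because it rests on 1 pair of arrays and no other pair was compared. MCT 2 also shared its slide with MCT 3, and saline 3 shared its slide with saline 1 and saline 2. A weaker response of the MCT 2 rat may explain the pattern and also stays open, as a hypothesis that no measure of disease severity used here can test.

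MCT 1 and MCT 3 were dimmer than the other 4 arrays. The slide or scan is argued against, since MCT 2 was 2.95 times as bright as MCT 3 on slide 2. A loss of circRNA with linear RNA kept is argued against in the labelled RNA only. The linear probes measure what RNase R left, so whether linear RNA was kept in the lungs cannot be judged. Before scaling, 20 linear probes fell by a median of 1.23 on MCT 1 and by a median of 1.37 on MCT 3. The 7316 circRNAs fell by 0.98 and 1.44, so the linear drop was 0.956 to 1.25 times the circRNA drop. Less labelled RNA of every kind on these 2 arrays is consistent with that ratio. Whether the treatment or the preparation lowered it stays open, as both dim arrays are MCT samples.

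Without a filter on dim probes, circRNAs higher in MCT outnumbered lower ones, 1433 to 738, by the looser criterion. Over the 1827 circRNAs not well above background on any array, the median log2 difference was 0.98 after scaling and 0.18 before it. Scaling shifts the difference of every probe by the same amount, so this rise was fixed in advance. What sets these circRNAs apart is the 0.18 before scaling, against -0.84 for the tested circRNAs. The surplus may therefore come from the floor of the processed signal, which the scaling raises on the dim MCT arrays.

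The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. At an adjusted p below 0.05, the real grouping gave 2 circRNAs, the highest other grouping gave 0, and 1 of the 10 splits reached the real count. By the looser criterion the real grouping gave 1302, the highest other gave 1602 (saline 3, MCT 1 and MCT 2 against the rest), and 3 of the 10 splits reached the real count.

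Of 20 array probes that carry no accession, 4 lay well above background on at least 3 arrays, and none of the 4 differed between the groups (lowest limma adjusted p = 0.32; 0 at an unadjusted p below 0.05).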
